A study of Homo sapiens with 6 samples.

How the data were processed

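Total RNA of cultured MDA-MB231 cells, an established line from a metastatic breast cancer, was labelled with biotin and hybridised to single-colour gene expression arrays, per the labels' protocols. There were 3 arrays of parental control cells and 3 arrays of 1 clone in which G9a had been stably knocked down, and each sample's group and replicate number came from its title. Per the labels, cells were harvested during logarithmic growth. The method and sequence used for the knockdown, and the way in which replicates were prepared, are not given in the sources used here.

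The log2 values had been summarised and scaled by the authors before they were deposited, with 1 value per probe set and array; the software and the method are not given in the sources used here. The log base is not stated either, and the values were taken as log2 intensities from their range alone, 2.13 to 14.8; that the arrays had been scaled to each other was likewise inferred from quartiles that were close but not identical on the 6 arrays. Array medians lay between 7.79 and 7.86. For these arrays no detection call or background value was used, so low values were not separated from background, and the number of arrays limits the precision.

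Of 33297 probe sets, 19460 were paired with 1 gene symbol in the platform's annotation, 1754 with several, and 12083 were not listed there and stayed unnamed. Symbols were updated through the Entrez gene number against the RefSeq gene table of GRCh38.p14, in which 19429 of the 19460 were found. A gene with several single-gene probe sets (769 genes) was represented by the one with the highest mean over the 6 arrays, which left 18417 genes. A gene whose only probe set carries several symbols was not tested by name. The same RefSeq table gave the order of neighbouring genes; its coordinates were not used otherwise, since the array data name no genome build.

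Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend) on the log2 values, knockdown minus control, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the 18417 genes. A gene was called changed at an adjusted p of 0.05, and a second count required a change of 2-fold or more. The test was two-sided. The design had 4 residual degrees of freedom. Replicate numbers come from the titles and do not pair the samples: the correlations of the deviations from the group means for arrays with the same number were -0.246, 0.122 and 0.0877.

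A total of 25 gene lists were fixed before the data were examined, and 544 of their 616 genes were measured singly. They covered epithelial, mesenchymal, luminal and basal genes, H3K9 methylation machinery, metastasis and invasion, inflammatory cytokines with NF-kappaB, interferon-stimulated genes, antigen presentation, proliferation, p53 targets with CDK inhibitors, serine synthesis with ATF4 targets, glycolysis with gluconeogenesis, hypoxia, cholesterol synthesis, TGF-beta response, germline and cancer-testis genes, imprinted genes, neuronal genes, autophagy, immediate early and heat shock stress genes, ribosomal proteins, housekeeping genes, and markers of leukocytes and of fibroblasts with endothelial cells. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists. Camera with an estimated correlation and fry were alternatives. Members were counted after adjustment over all genes and after adjustment over the list alone. For each list, 10000 random lists of the same size matched on mean expression in 50 bins were drawn.

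The genes named were chosen by a rule set before the data were examined: EHMT2, CDH1, SNAI1, SNAI2, VIM, CDH2, FN1, CLDN1, CLDN3, CLDN4, CLDN7, FBP1 and ESR1 always; the 12 largest rises and the 12 largest falls past the threshold with no overlap between the groups; and from each list up to 4 members past the threshold with the largest change, or the 2 largest where none passed. The rule also left out multigene families whose probe sets match several genes; this was applied only through probe sets with several symbols in the annotation, so the paralogs SSX1 and SSX6P, and SAA1 and SAA2, stayed among the named genes, which departs from the rule as written. Genes named outside that rule are marked as chosen after their values were seen.

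The steps were tested on simulated arrays. Each simulated gene had normal noise, with a spread drawn from the distribution of spreads that limma had fitted to the real genes. Among 18417 simulated genes with 200 changed, 71.0% of changes of 0.5 log2 and 98.0% of changes of 1 log2 were recovered, none with the wrong sign, beside 8 false calls (4.52% of calls). A simulated shift of -0.3 in 1 list was recovered as -0.31 and called, and 0 of the 24 other lists were called by camera. The simulated noise followed limma's own model, so good recovery and few false calls were built in. Simulated genes varied independently and no simulated array stood apart. These figures therefore do not show how reliable the gene calls are on the real arrays, or how camera treats lists whose members move together. In the real data the cytokine and cholesterol synthesis lists had estimated correlations of 0.70 and 0.49 between members.

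Alternatives were quantile normalization, median centring, leaving out the genes in the lowest 33.3% of mean expression, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, the replicate number as a block, every probe set tested on its own, and leaving out each array in turn. An offset before log2 transformation had been foreseen for linear values and was not needed. Leaving out control replicate 3 and knockdown replicate 1 together was added after seeing the data, because the second principal component set them apart. The value of EHMT2 with every probe set tested was also added after the results were seen. Neighbouring genes were compared as medians of 39 consecutive genes outside the lowest 33.3% of mean expression, against 1000 shuffles of the gene order; 40 had been foreseen, and a running median needs an odd width. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.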

Results

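Gene expression was measured on 6 arrays of MDA-MB231 cells, a metastatic breast cancer line: 3 of parental cells, called control here, and 3 of 1 clone with a stable knockdown of G9a. G9a, encoded by EHMT2, is a histone methyltransferase that places repressive methyl marks on histone H3. The comparison asked how the clone differed from the parental cells. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson r between pairs of arrays, across probe sets, which are not independent replicates, ran from 0.992 to 0.997, and no pair held identical values. Differences are knockdown minus control on the log2 scale with the standard error from limma, n = 3 arrays per group.

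EHMT2 fell by 0.55 ± 0.10 (SE) on the log2 scale in the knockdown, to 0.681 of the control level (limma, adjusted p = 0.0259). Its mean was 10.14 ± 0.18 in control and 9.58 ± 0.07 in the knockdown (SD, n = 3), and the groups did not overlap. The control arrays read 10.21, 10.27 and 9.93 and the knockdown arrays 9.66, 9.59 and 9.51. EHMT2 had 2 probe sets with identical values on all 6 arrays, which count as 1 measurement. The difference stayed negative with any array left out, but the adjusted p was 0.0743 without control replicate 1, 0.0778 without control replicate 2, and 0.0764, 0.0716 and 0.122 without knockdown replicates 1, 2 and 3. Without control replicate 3 it was -0.66 (adjusted p = 0.0101). With every probe set tested, which was added for this gene after the results were seen, the adjusted p was 0.0957.

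Among the genes that passed the test, the largest rises were those of F13A1, the A subunit of coagulation factor XIII (3.49-fold), CXCL10, an interferon-inducible chemokine (2.70-fold), CCDC190 (2.46-fold), the long noncoding RNA UCA1 (2.39-fold) and the cancer-testis gene SSX1 (2.27-fold), and these were the 5 genes that rose 2-fold or more. SSX6P, RTL3, MISP, PDE7B, SPP1 (osteopontin), TLR4 and MGP (matrix Gla protein) followed, at 1.94-fold to 1.79-fold. The largest falls among the genes that passed were those of IL1A, encoding interleukin-1 alpha (3.78-fold lower), the acute phase genes SAA1 (3.64-fold lower) and SAA2 (3.37-fold lower), TMEM154 (3.24-fold lower) and CXCL1, a neutrophil chemokine (2.54-fold lower). LUM (lumican), HHIP, a hedgehog antagonist, ATF7IP2, INSIG1, IL24, SLCO4C1 and LOX, which crosslinks collagen, fell by 1.31 to 1.11 on the log2 scale. SSX1 with SSX6P, and SAA1 with SAA2, are close paralogs whose probe sets may share signal, so their separate values are uncertain.

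Of 18417 genes, 235 rose and 327 fell (limma, adjusted p of 0.05), 5 and 19 of them by 2-fold or more. A further count, of genes whose groups did not overlap, was 2628 higher and 2338 lower; chance gives 10% of genes for 3 arrays against 3. The number of calls depended on the arrays: 230, 146 and 535 genes passed without control replicates 1, 2 and 3, and 70, 198 and 44 without knockdown replicates 1, 2 and 3, with every one of the 562 genes keeping its sign. Of the 83 genes named by the rule, 55 passed; 15, 23 and 3 of these missed the threshold without control replicates 1, 2 and 3, and 35, 23 and 38 without knockdown replicates 1, 2 and 3. There were 16 that passed in each of the 6 fits: F13A1, UCA1, SSX1, SSX6P, MISP, MGP, TAGLN and ITGB4 among the rises and SAA2, TMEM154, LUM, HHIP, IL24, LOX, ADAMTS1 and KDR among the falls. With control replicate 3 and knockdown replicate 1 left out together, 10 of the 55 missed the threshold: RTL3, MUC1, ELF3, MX2, ID1, SCG2, CDS1, TNFAIP3, SYT1 and MAP2, with adjusted p from 0.0501 to 0.0789. Of the 28 named genes that did not pass, 11 passed with array weights: SNAI2, CLDN1, AGR2, KDM7A, PSMB10, CCNE2, GRB10, RPL32, RPS14, CSF1R and PTPRC. With a variance trend 5 passed: SNAI2, CLDN1, KDM7A, TAPBP and RPL32.

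**Figure D1:**
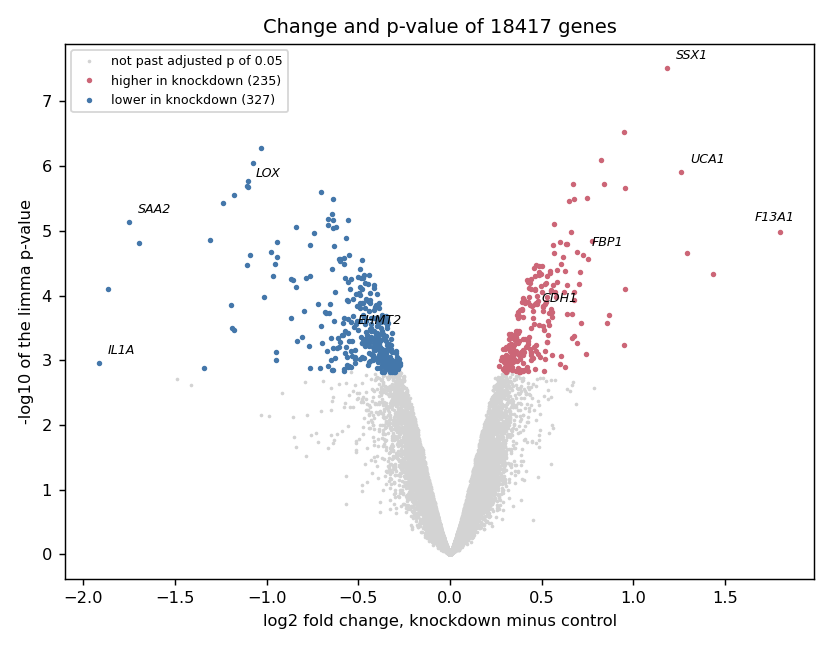
Each point is 1 of 18417 genes, with the log2 fold change (knockdown minus control, 3 arrays each) on the horizontal axis and -log10 of the limma p-value on the vertical axis; colours mark the 235 genes that rose and the 327 that fell at an adjusted p of 0.05. SSX1 has the smallest p, F13A1 the largest rise and IL1A the largest fall.

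Neighbouring genes moved together. In the gene order of GRCh38.p14, 1070 of 11366 windows of 39 genes had a median past the bound from shuffled gene order (0.126 from the median of all genes), and they formed 19 runs, 11 lower and 8 higher. The longest were lower: a run from WFS1 to FRG1 had a median of -0.18 relative to all genes, with 84.0% of its 382 genes outside the lowest 33.3% of mean expression at negative values, and a run from ZCCHC9 to SNORD96A had a median of -0.19, with 79.3% of 347 such genes. These 2 runs held 6.26% of all genes tested, 30.6% of the falls (100 of 327) and 4.68% of the rises (11 of 235), and the 19 runs together 15.6% of genes, 47.7% of the falls and 21.7% of the rises. The WFS1 to FRG1 run spanned 638 tested genes and the ZCCHC9 to SNORD96A run 514, so these shifts are not confined to small neighbourhoods. None of the other runs held more than 144 genes outside the lowest 33.3% of mean expression. Since the runs were picked by the medians of the same values, an excess of calls in them is partly built in. Among the named genes, TMEM154, CXCL1, HHIP, CDS1 and KDR (lower) and CXCL10 and SPP1 (higher) lay in the first run, and SLCO4C1, LOX, P4HA2, STARD4 and EGR1 (lower) in the other, as did RPS14 and CSF1R, which did not pass. SAA1 and SAA2, FOS, MYLK, FBP1 and RPL32 lay in shorter runs that moved in the same direction as these genes.

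Epithelial genes moved both ways. CDH1, encoding E-cadherin, rose by 0.45 ± 0.07 (1.37-fold; limma, adjusted p = 0.0177), from 7.16 ± 0.11 to 7.61 ± 0.03 (SD, n = 3), and MUC1 (0.39) and ELF3, an epithelial transcription factor (0.38), rose too, while the phospholipid enzyme gene CDS1 fell by 0.40. Of 39 measured epithelial junction and identity genes, 4 rose, 2 fell and 33 did not pass; adjusted over the list alone, 7 rose and 4 fell. The list's median was 0.05, with no call by camera (adjusted p = 0.656); it was 0.01 without control replicate 1, 0.02 without knockdown replicate 1 and 0.09 without control replicate 3. The claudins CLDN3 (0.02), CLDN4 (0.17), CLDN7 (0.05) and CLDN1 (-0.47, adjusted p = 0.107) did not pass, and CLDN3 and CLDN7 changed sign without control replicate 1, to -0.03 and -0.0025. Without control replicate 3, CLDN1 was at -0.29 and passed (adjusted p = 0.0471), as it did with a variance trend (0.0463) and array weights (0.0240). ELF3 missed the threshold after quantile normalization (0.0608) and median centring (0.0583). CDH1, which lay in the lowest 33.3% of mean expression, missed the threshold in the 5 fits without another array, with adjusted p from 0.0525 to 0.0983, and passed without control replicate 3 (0.0119).

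Among mesenchymal and EMT regulator genes, TAGLN (transgelin, 0.56), S100A4 (0.49) and COL6A1, a collagen VI chain (0.44), rose, and LOX fell by 1.11. Of 39 measured members, 3 rose, 1 fell and 35 did not pass; adjusted over the list alone, 4 rose and 1 fell. The median was 0.06, without a call (adjusted p = 0.305), although array weights gave 0.10 (adjusted p = 0.0387), and it was 0.10 without control replicate 3 (adjusted p = 0.0924). SNAI1 (-0.11 ± 0.08), SNAI2 (0.27 ± 0.09), the intermediate filament gene VIM (-0.04 ± 0.05), CDH2 for N-cadherin (-0.09 ± 0.07) and the fibronectin gene FN1 (0.07 ± 0.07; all SE) did not pass, with adjusted p from 0.133 to 0.752; SNAI2 passed with a variance trend (0.0489) and array weights (0.0285). With 1 array left out, SNAI1 ranged from -0.16 to -0.04, CDH2 from -0.14 to -0.05 and FN1 from 0.02 to 0.11. Knockdown replicate 3 was the array without which SNAI1 and FN1 lay nearest to 0.

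**Figure D2:**
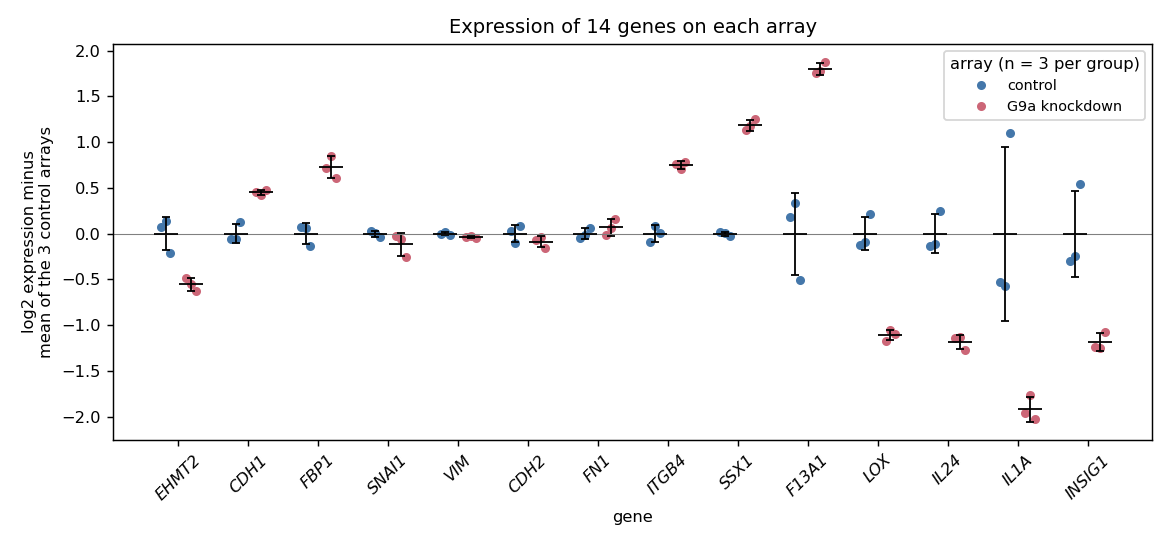
Log2 expression of 14 genes on each array, minus the mean of the 3 control arrays; points are arrays, and black bars show the mean and SD of 3 arrays per group. EHMT2 lies lower and CDH1 and FBP1 higher on every knockdown array than on every control array, and the control array far above the others for IL1A and INSIG1 is replicate 3.

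The basal list rose in the knockdown, with the laminin receptor subunit gene ITGB4 (0.75) and MYLK, a myosin kinase gene (0.63), passing. Of 14 measured basal genes, 2 rose, 0 fell and 12 did not pass, with the same counts adjusted over the list alone; the median was 0.11 (camera, adjusted p = 0.0333; adjusted p = 0.483 with an estimated correlation). This call was lost without control replicate 1 (0.0638), control replicate 2 (0.0785) or knockdown replicate 3 (0.0944). None of 20 luminal genes passed, over all genes or adjusted over the list alone, and the estrogen receptor gene ESR1 (0.07), XBP1 (-0.23) and AGR2 (-0.21) are given as values. They moved with single arrays, ESR1 from 0.03 without control replicate 1 to 0.13 without knockdown replicate 3, XBP1 to -0.14 without control replicate 3 and AGR2 to -0.08 without knockdown replicate 2. The luminal median (0.02) and mean (0.0052) were positive where camera's direction was down (adjusted p = 0.927).

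Genes of cholesterol synthesis were lower as a group. INSIG1, a sterol sensor partner (-1.19), HMGCS1, which makes HMG-CoA (-0.95), SC5D, a late-step desaturase (-0.86), and STARD4, a sterol carrier (-0.84), had the largest falls among the members that passed. All 18 measured members had negative values; 6 fell and 12 did not pass, and adjusted over the list alone 15 fell. The median was -0.44 (camera, adjusted p = 1.24e-14, and 0.483 with an estimated correlation), and fry did not call the list (adjusted p = 0.0721). Control replicate 3 had the highest list level, 0.51 above the mean of the 6 arrays, against 0.13 and 0.14 in the other control arrays and -0.31 to -0.23 in the knockdown; without it the median was -0.30 and 9 members fell. INSIG1 missed the threshold without knockdown replicates 1, 2 and 3 (adjusted p = 0.103, 0.0682 and 0.0969).

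Inflammatory cytokine and NF-kappaB genes were also lower. IL1A fell by 1.92, CXCL1 by 1.34, IL24 by 1.18 and TNFAIP3, a feedback inhibitor of NF-kappaB, by 0.58 on the log2 scale. Of 23 measured members, 6 fell, none rose and 17 did not pass; adjusted over the list alone, 11 fell and 1 rose. The median was -0.25 (camera, adjusted p = 8.11e-09, and 0.499 with an estimated correlation), and fry did not call the list (adjusted p = 0.172). In runs of neighbouring genes lay 9 members, CXCL1 among them. The list level was 0.59 above the 6-array mean on control replicate 3, 0.06 and 0.10 on the other control arrays and -0.28 to -0.20 on the knockdown arrays; the median was -0.13 without control replicate 3, with 8 members lower, and -0.39 without control replicate 1. IL1A missed the threshold without control replicate 2 (adjusted p = 0.0527) or knockdown replicates 1, 2 or 3 (0.150, 0.0873 and 0.155), and was at -1.37 without control replicate 3. CXCL1 and TNFAIP3 passed with 1 array left out only without control replicate 3, with adjusted p from 0.0535 to 0.160 and from 0.0593 to 0.171 in the other fits, and missed the threshold after quantile normalization (0.0533 and 0.0510).

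Serine synthesis and ATF4 target genes had a median of -0.29 over 24 members, but SLC7A5, an amino acid transporter gene, rose by 0.42 and was the member that passed, over all genes and adjusted over the list alone; none fell and 23 did not pass. Camera called the list lower (adjusted p = 2.96e-06, and 0.499 with an estimated correlation), and fry did not call it (adjusted p = 0.302). Control replicate 3 lay 0.52 above the 6-array mean for this list, the other control arrays at -2.09e-04 and -0.0070 and the knockdown arrays from -0.19 to -0.14. Without control replicate 3 the median was -0.14 (adjusted p = 9.96e-07) with 1 member higher and 5 lower: ASNS, CHAC1, DDIT3, CTH and VLDLR, named after their values were seen.

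Hypoxia genes were lower, with LOX (-1.11), the glucose transporter gene SLC2A1 (-0.48) and the collagen hydroxylase gene P4HA2 (-0.36) passing. Of 19 members, 3 fell, none rose and 16 did not pass, and adjusted over the list alone 7 fell and 1 rose; the median was -0.18 (camera, adjusted p = 2.32e-06; adjusted p = 0.413 with an estimated correlation) and -0.12 without control replicate 3. Of 23 glycolysis and gluconeogenesis genes, FBP1, a gluconeogenic phosphatase gene, rose by 0.72 ± 0.09 (SE; limma, adjusted p = 0.00872), ALDOC, an aldolase gene, fell by 1.11 and SLC2A1 fell by 0.48; 20 did not pass, and adjusted over the list alone 1 rose and 3 fell. FBP1 missed the threshold without knockdown replicate 1 (adjusted p = 0.0503). The median of the glycolysis list was -0.04 (camera, adjusted p = 0.0333, and 0.483 with an estimated correlation), and 9.02% of its random lists of matched expression had a median as low. The glycolysis call was lost after quantile normalization (0.144) and with the lowest 33.3% of genes left out (0.104). It was also lost without control replicate 2 (median -0.01, 0.0805) or knockdown replicates 1 (0.0722) or 3 (median -0.02, 0.0546). Without control replicate 3 the median was -0.07.

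Immediate early and heat shock stress genes were lower in the knockdown, with the transcription factor genes EGR1 (-0.95) and FOS (-0.41) passing. Of 20 members, 2 fell and 18 did not pass, and adjusted over the list alone 5 fell; the median was -0.06 (camera, adjusted p = 0.00241; adjusted p = 0.483 with an estimated correlation) and -0.10 without control replicate 1. Control replicate 3 lay highest on the stress list, 0.17 above the 6-array mean against 0.01 and 0.05 in the other control arrays; without it the median was -0.05 (adjusted p = 0.00932). BECN1, an autophagy regulator gene, fell by 0.40 as the 1 passing member of 20 autophagy genes, 3 adjusted over the list alone. The autophagy list's median was -0.02 (camera, adjusted p = 0.0350, and 0.499 with an estimated correlation), and 22.9% of its random lists of matched expression had a median as low. The autophagy call was lost after quantile normalization (0.0841), with the lowest 33.3% of genes left out (0.122), with array weights (0.127), with control replicate 3 and knockdown replicate 1 left out together (0.286), and without control replicate 3 (0.134), knockdown replicate 1 (0.117) or knockdown replicate 3 (0.0743), and its median was -0.04 without control replicate 1, control replicate 2, knockdown replicate 1 or knockdown replicate 2 and -0.0039 without knockdown replicate 3.

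Of 34 proliferation genes none passed, over all genes or adjusted over the list alone; CCNE2 (0.42) and MCM4 (0.34) had the largest values, which were 0.23 and 0.18 without control replicate 3. Camera called the list higher (median 0.10, adjusted p = 0.0350; adjusted p = 0.924 with an estimated correlation), but control replicate 3 lay at -0.17 on this list, the other control arrays at 0.03 and -0.0039 and the knockdown arrays at 0.01 to 0.07. The call was lost without control replicate 3 (median 0.05, adjusted p = 0.424), knockdown replicate 2 (0.284) or knockdown replicate 3 (0.124), with array weights (0.127), and with control replicate 3 and knockdown replicate 1 left out together (0.105), a setting added after seeing the data. No list was called by camera with an estimated correlation.

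**Figure D3:**
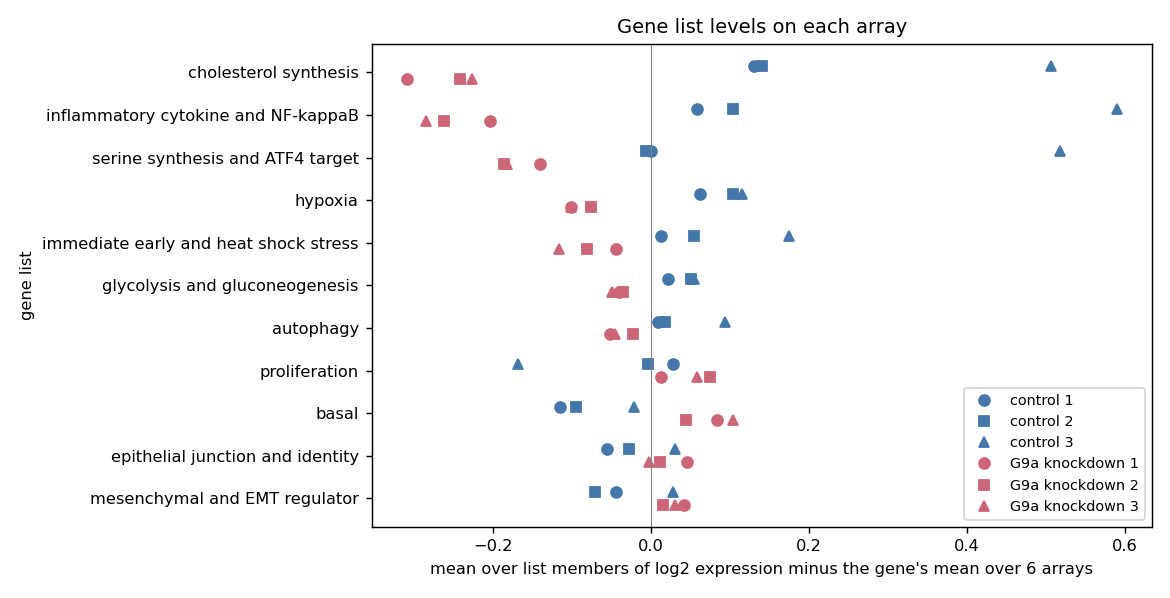
Level of 11 gene lists on each array, as the mean over members of log2 expression minus the gene's mean over the 6 arrays; colours mark the group and shapes the replicate. Control replicate 3 lies apart from the other control arrays for cholesterol synthesis (0.51), inflammatory cytokines (0.59) and ATF4 targets (0.52).

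Metastasis and invasion genes moved in both directions: SPP1 (0.87) and VCAM1, an adhesion molecule gene (0.68), rose, and CXCL1 (-1.34) and the protease gene ADAMTS1 (-0.64) fell. Of 31 members, 5 rose, 4 fell and 22 did not pass, and adjusted over the list alone 9 rose and 7 fell; camera made no call (median 0.07, adjusted p = 0.742; 0.03 without control replicate 2). Of 25 genes of the H3K9 methylation machinery none passed, over all genes or adjusted over the list alone, with KDM7A, a histone demethylase gene, at -0.92 (adjusted p = 0.0685) and UHRF1 at 0.29 (0.13 without control replicate 3); KDM7A passed without control replicate 3 (-0.63, adjusted p = 0.0378), after median centring (0.0422), with the lowest 33.3% of genes left out (0.0461), with a variance trend (0.0286) and with array weights (0.0272). The H3K9 list's median was 0.01, its mean -0.03 and camera's direction down (adjusted p = 0.742).

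SSX1 was the 1 member that rose of 25 germline and cancer-testis genes, 3 adjusted over the list alone, and the list was not called (median 0.07, adjusted p = 0.181). With the lowest 33.3% of genes left out it kept 2 members, CTAG2 and SSX1, and was called (median 0.66, adjusted p = 0.0151). With 1 array left out its median ranged from 0.03 without control replicate 1 to 0.11 without knockdown replicate 2. Of 27 neuronal genes, SCG2 rose by 0.55, SYT1 fell by 0.42 and MAP2 fell by 0.39, and adjusted over the list alone 1 rose and 3 fell (median 0.06, adjusted p = 0.742; 0.02 without knockdown replicate 1 and 0.12 without control replicate 3). None of 15 imprinted genes passed either adjustment, with GRB10 at -0.24 and MEST at 0.23 (median 0.05, adjusted p = 0.742; -0.0083 without control replicate 2 and 0.10 without control replicate 3). ID1, a target of TGF-beta family signalling, rose by 0.60 as 1 of 23 TGF-beta response genes, and adjusted over the list alone 5 rose and 1 fell. The median of this list was -0.0028, the mean 7.58e-04 and camera's direction down (adjusted p = 0.927). MX2, an antiviral gene, rose by 0.38 as 1 of 35 interferon-stimulated genes, and adjusted over the list alone 2 rose and 2 fell (median 0.06, adjusted p = 0.561; -0.05 without control replicate 3, which lay lowest on this list at -0.21). MX2, ID1 and MAP2 missed the threshold in each of the 6 fits with 1 array left out, with the lowest adjusted p 0.0545, 0.0580 and 0.0532 without control replicate 3, and MX2 also after quantile normalization (0.0595) and median centring (0.0588).

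No gene of the antigen presentation, p53, ribosomal protein or housekeeping lists passed, over all genes or adjusted over the list alone. There were 15 antigen presentation genes (PSMB10 0.23, TAPBP 0.16; median 0.04, adjusted p = 0.800) and 19 p53 target and CDK inhibitor genes (TP53I3 0.26, CDKN2D 0.25, or 0.14 without knockdown replicate 1; median 0.0085, adjusted p = 0.990). There were 30 ribosomal protein genes (RPL32 0.30, RPS14 -0.17; median -0.03, adjusted p = 0.114; -0.04 without control replicate 3 and -0.01 without knockdown replicate 3) and 9 housekeeping genes (GUSB 0.18, or 0.09 without control replicate 3, and TFRC -0.14; median -0.0054, adjusted p = 0.656). RPL32, with an adjusted p of 0.0631, passed after quantile normalization (0.0392), with the lowest 33.3% of genes left out (0.0338), with a variance trend (0.0302) and with array weights (0.0105). Of markers of other cell types, none of 14 leukocyte genes passed either adjustment (CSF1R 0.22, PTPRC 0.21; median 0.07, adjusted p = 0.480; 0.0084 without control replicate 1). Of 14 fibroblast and endothelial markers, CDH5 for VE-cadherin rose by 0.71, and LUM (-1.31) and KDR, a VEGF receptor gene (-0.64), fell. Adjusted over the list alone, 2 rose and 2 fell, and the median was 0.06, the mean -0.0048 and camera's direction up (adjusted p = 0.921). That median was 0.0056 without knockdown replicate 1.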

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

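Leaving out control replicate 3 and knockdown replicate 1 together, and EHMT2's value with every probe set tested, were chosen only after the data were seen; all other settings were fixed before the data were examined. Every one of the 562 called genes kept its sign in each setting that tested it, and EHMT2 stayed past the threshold in the settings that kept all 6 arrays and tested genes, but with every probe set tested its unchanged -0.55 had an adjusted p of 0.0957. The genes that rose and fell numbered 398 and 574 with the lowest 33.3% of genes left out, where fewer genes were tested. They numbered 438 and 649 with a variance trend and robust estimation, and 1718 and 1610 with array weights. With the 2 arrays left out they were 154 and 189, and among all probe sets, where more tests were adjusted, 27 and 33. The number of tests was not the only change. For the same difference, EHMT2 had a standard error of 0.0958 in the main fit, 0.0929 with the lowest 33.3% of genes left out and 0.102 among all probe sets. The cause of these changes in the counts was not tested. Array weights gave control replicate 3 a weight of 0.273 and control replicate 2 one of 4.83. With the replicate number as a replicate block, 101 rose and 116 fell, and 12 named genes lost and 1, KDM7A, gained a call; the labels' numbers do not pair the samples (correlations of deviations -0.246, 0.122 and 0.0877), so this says nothing about a weaker effect. With 1 array left out, rises ranged from 21 to 222 and falls from 23 to 313, rises of 2-fold or more from 3 to 7, falls of 2-fold or more from 9 to 24, and EHMT2 from -0.66 to -0.49; fewer samples entered these fits. The mesenchymal median of 0.10 with array weights passed, and the epithelial list kept its sign and stayed uncalled in every setting. These values reversed, all in results that were not called: ESR1 -0.0070, antigen presentation -0.0127, interferon-stimulated -0.0342 and luminal -0.0146 with array weights; H3K9 machinery -0.0093 and p53 targets -0.0118 with median centring, which moved every gene by the same -0.0203; housekeeping 6.44e-04 and p53 targets -0.0130 with quantile normalization; and TGF-beta 0.0239, antigen presentation -0.0254 and interferon-stimulated -0.0254 with the 2 arrays left out; outside median centring the cause was not tested. With 1 array left out the epithelial median ranged from 0.0114 to 0.0859, and the ranges that crossed 0 were -0.0095 to 0.0608 (antigen presentation), -0.0257 to 0.0859 (CLDN3), -0.0025 to 0.14 (CLDN7), -0.0070 to 0.0459 (H3K9 machinery), -0.0332 to 0.0078 (housekeeping), -0.0083 to 0.10 (imprinted), -0.0457 to 0.11 (interferon-stimulated), -7.33e-04 to 0.0539 (luminal), -0.0223 to 0.0556 (p53 targets) and -0.0592 to 0.0247 (TGF-beta). Fry kept the calls of the basal, glycolysis and hypoxia lists (adjusted p = 0.0493, 0.0382 and 0.0102). It lost the calls of 6 of the 9 lists called by camera, with adjusted p from 0.0721 to 0.472. These were cholesterol synthesis, inflammatory cytokines, ATF4 targets, immediate early and stress genes, autophagy and proliferation. An estimated correlation lost all 9. No offset was tried, since the values were already on a log scale, and without background values the limit set by dim signal was not measured.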

Other observations

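Tests chosen only after the result was seen were the counts of list members lower without control replicate 3 and the margin of 1 bootstrap standard error around the leave-one-out medians, without which both medians would have stayed past their bounds and argued against control replicate 3 as setting most of the size. The tests on the 2 longest runs and on cytokine genes outside runs were set once the runs were known, before their own values were computed.

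Neighbouring genes moved together in the clone: 1070 of 11366 windows of 39 neighbouring genes had a median farther from that of all genes than 0.126 on the log2 scale, the bound that the largest window passed in 5% of 1000 shuffles of gene order, and they formed 11 lower and 8 higher runs. Gene density and gene length are argued against as the whole cause of the 2 longest runs, since the less preserved of them kept 75.3% of its median after a loess fit on both. The spread between arrays of 1 group stays open, because the runs were picked on the same arrays. In the WFS1 to FRG1 run the gap between groups was 0.11, 1.24 times the larger range within a group (0.09). In the ZCCHC9 to SNORD96A run the gap was 0.16, against a range of 0.03 within each group. A copy number difference carried by the clone is a candidate explanation, as it needs such windows and the test could have found none. Base composition and regional regulation by G9a were not tested, and with 1 clone no comparison here separates a property of that clone from the knockdown.

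The lower cytokine list is argued not to come from array scaling, since its median relative to all genes was -0.26 after quantile normalization, nor from an intensity trend, since 0 of 10000 random lists of matched expression had a median as low. It does not rest wholly on control replicate 3, without which 8 members fell against 6 with all arrays. Whether that array sets most of the size cannot be told apart from the knockdown, because the median without it, -0.13, lay within its bootstrap standard error of 0.12 of the bound of -0.13. A copy number difference may contribute, with 9 of 23 members in runs. The 14 members outside had a median of -0.22 with a bootstrap standard error of 0.14, too wide to decide. The 9 in runs were CXCL8 (-1.49), CXCL2 (-1.41), CXCL1 (-1.34), NFKBIA (-0.40), NFKB2 (-0.35), CCL2 (-0.20), CXCL3 (-0.19), CCL5 (-0.01) and CXCL5 (0.07). The run that holds CXCL1 had a median of -0.16 before the median of all genes was subtracted. A shift of that size alone would be too small for the fall of CXCL1. The knockdown and the state of the cultures, which the labels do not describe by array, both stay open.

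The lower cholesterol synthesis list is likewise argued not to come from array scaling (median -0.45 relative to all genes after quantile normalization), from an intensity trend (0 of 10000 random lists as low) or wholly from control replicate 3 (9 members fell without it, 6 with all arrays). How much of its size that array sets cannot be told apart from the knockdown: the median without it was -0.30, and its bootstrap standard error of 0.11 reaches the bound of -0.22. Only 2 of its 18 members lay in runs, and the 16 others had a median of -0.39. The knockdown and the state of the cultures may both contribute, and neither was tested.

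The real grouping gave 235 rises and 327 falls, and the highest of the other 9 splits of the 6 arrays into 3 and 3 gave 0 calls with limma, with 226 to 2534 genes at an unadjusted p of 0.05 against 3568. The 2534 came from control replicates 1 and 2 with knockdown replicate 2 against the other arrays, and the next highest was 712. The sign of the second principal component (28.1% of variance) divided the arrays in the same way, but knockdown replicate 3 lay near 0 on it (-0.16). Control replicate 3 was at -14.8 and knockdown replicate 1 at -9.51. Control replicates 1 and 2 were at 10.5 and 5.94, and knockdown replicate 2 at 8.09. Each of the other splits mixes the groups, so a difference between groups widens the spread within each side, and 0 calls there decides nothing. For both directions 1 of the 10 splits, the real one, gave as many genes, and with 10 splits the share cannot be under 0.1.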
